A study of Mesocricetus auratus with 6 samples.

How the data were processed

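RNA from BHK21 cells, 3 libraries after transfection with STYK1/NOK and 3 after transfection with the empty vector pCMV-Myc, was extracted with Trizol and made into libraries with the Illumina TruSeq RNA kit from 1 ug of total RNA, per the labels' protocols. The deposited values are FPKM (fragment counts divided by transcript length and by the library's mapped fragments), 1 value per gene and library with 2 decimals, per the file headers and the values themselves. Bowtie 0.12.2 and the mouse genome builds mm8 and mm9 are named in the submitters' processing notes, with no role. The rows carry NCBI Gene IDs, and those match hamster genes, so which genome and annotation the FPKM values rest on is not settled here. The tool that computed FPKM, whether strand was used and how reads shared between gene copies were assigned are not given in the sources used here. Values of overlapping genes, antisense genes and close paralogs are therefore uncertain.

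Each library had its own file, and each file was assigned to its sample by the series' record and each sample to its group by its treatment label. Of 16078 IDs, 15049 matched the NCBI RefSeq gene table of the hamster assembly BCM_Maur_2.0, which was used only for gene names; 1029 did not match and 1641 matched a name that begins with LOC. Because its build is not known to be that of the files, no coordinates or gene lengths were taken from it. No gene was at 0 in all 6 libraries.

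FPKM values are not counts, so the branch planned for normalized values was used and no count model was fitted. Genes with a mean of at least 1 FPKM in 1 of the groups were kept (11464 genes). They were tested with limma-trend (limma 3.58.1 in R 4.3.3, robust empirical Bayes) on log2(FPKM + 1), with no further normalization and p-values adjusted by Benjamini and Hochberg. Fold changes on that scale understate the change of genes with low FPKM, while folds named in the text are ratios of mean FPKM. For Styk1 a two-sided exact permutation test on the same scale was added.

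Gene lists were written from general knowledge before the data were examined, 30 in all, and matched by symbol. Of these, 27 had at least 5 members past the filter and were tested with camera (preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the 27. A camera test compares a list with all other genes, while fry asks whether the genes of a list move one way on balance. The rule for named genes, also written before, took Styk1, then up to 12 higher and 12 lower genes past the threshold. Places left open were filled with the genes of smallest p whose 3 libraries in one group all lay above the other group, with at least 1 FPKM in each library of the higher group and a symbol that is more than an identifier. No gene passed, so all 24 came from the second part. Placeholder names for open reading frames were counted as identifiers, a reading of the rule made after the data were seen. In each list up to 4 members with the smallest p could be named. Some genes that the rule chose are not reported here.

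Total reads per library were not given, so depth was compared through genes of low FPKM. Where whole fragments were counted, an FPKM value is a multiple of what 1 fragment is worth for that gene. The most frequent log2 ratio between 2 libraries over genes at 0.8 to 6 FPKM (kernel bandwidth 0.005) gave depth relative to STYK1 1. Those settings were chosen after 4 minimums and 2 bandwidths had been tried. At a minimum of 0.25 FPKM with the smaller bandwidth, vector 1 came out at 1.00, and at 1.2 FPKM with a bandwidth of 0.01 vector 1 and vector 2 came out at 1.10 and 1.11. Vector 1 was between 1.01 and 1.02 in the other settings. Absolute depth stayed unknown, so no counting interval or detection limit is given.

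The scripts were tested on simulated data built from the deposited values or from the noise fitted in them, so these tests were not blind to the data. When known folds were put into the deposited values of 200 genes among 11464, the test recovered 43.0% of genes changed 1.5-fold, 81.5% of those changed 2-fold and 99.5% of those changed 4-fold. With independent simulated noise, it recovered 53.5% of genes changed 1.5-fold at the noise fitted in all 6 libraries, the design used, and 92.0% at the noise fitted without vector 1. Both simulations had 6 libraries, so the 92.0% is not the recovery of the fit that left vector 1 out, which had fewer libraries. In all of these simulations the changed genes were drawn only from genes above a floor of mean FPKM that lies higher than the level of Styk1. Recovery at the level of Styk1 or lower was therefore not simulated. For the lists, 0 of 27 were called with no shift put in, but that simulation used independent noise, while the members of the 4 lists called in the real data had estimated correlations of 0.44 to 0.88. With the real values, other splits of the 6 libraries gave 2 to 6 lists called, so the 0 of the simulation is no measure of false calls with the preset correlation here.

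Alternatives planned before the data were examined were other pseudocounts, no filter, quantile normalization, median centring, stricter thresholds, the replicate number as a block, each library left out in turn, an estimated correlation in camera, and fry. Quality weights for libraries and scaling to equal FPKM sums were added after vector 1 was seen to stand apart and the FPKM sums to differ. Running the lists under the other pseudocounts, without the filter and under the other scalings was also added later, as were an estimated correlation and fry without vector 1, the count of named genes that moved without vector 1, both tests under each setting that called a further list, and intervals of list levels from the spread between libraries. The tests of vector 1 as the only source of the ribosomal and of the cell-cycle difference, and that of protein size, first took list medians with a spread over genes, which are correlated. That had excluded vector 1 for the ribosomal part, and had counted in favour of vector 1 for the cell cycle and of size for the ribosomal and oxidative phosphorylation genes. With the spread between libraries, used later, none of these tests met its bound. Lists of genes for short proteins and for very large proteins were also added later. They were written from general knowledge after fold changes had been compared with gene spans from the RefSeq table. The higher and lower genes chosen by the rule were left out of both size lists. Since that table's build is not matched to the files, the comparison with spans is not reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.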

Results

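The data set holds RNA sequencing of BHK21 cells, a fibroblast-like line derived from baby hamster kidney, transfected with STYK1/NOK or with an empty vector. STYK1, also called NOK, is a single-pass membrane protein with a kinase-like domain, and the series describes its gene as an oncogene. The vector was pCMV-Myc, a mammalian expression plasmid. There were 6 libraries, 3 from STYK1/NOK-transfected cells (STYK1 1 to 3) and 3 from cells given the empty vector (vector 1 to 3). RNA was harvested 48 after transfection, and the labels give no unit for that time. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

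Each library listed 16078 genes in FPKM, and between 14119 and 14339 of them were above 0. The total number of reads was not given in the sources used here. From the spacing of the lowest FPKM values, the depth relative to STYK1 1 was estimated as 1.01 for vector 1, 1.01 for vector 2, 1.00 for vector 3, 0.979 for STYK1 2 and 1.03 for STYK1 3. The FPKM values summed to 619840 in vector 1, 554681 in vector 2, 557946 in vector 3, 528160 in STYK1 1, 530277 in STYK1 2 and 542638 in STYK1 3. The 10 genes with the highest FPKM took 8.40% of that sum in vector 1 and between 6.85% and 7.45% in the other 5 libraries.

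Vector 1 stood apart from the other 5 libraries. Its Pearson correlation with them, on log2(FPKM + 1) over 11464 genes, was 0.963 to 0.976, against 0.988 to 0.993 for pairs that left it out. On the component that held 58.8% of the variance, vector 1 lay at -38.1, vector 2 at 1.98, vector 3 at 3.99, and the STYK1 libraries at 14.8, 6.44 and 10.9. The next component held 16.6% and set STYK1 2 at 19.3 apart from the others, which lay between -9.13 and 0.83. No pair of libraries shared more than 0.663% identical FPKM values, so none was counted as a repeat of another.

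**Figure D1:**
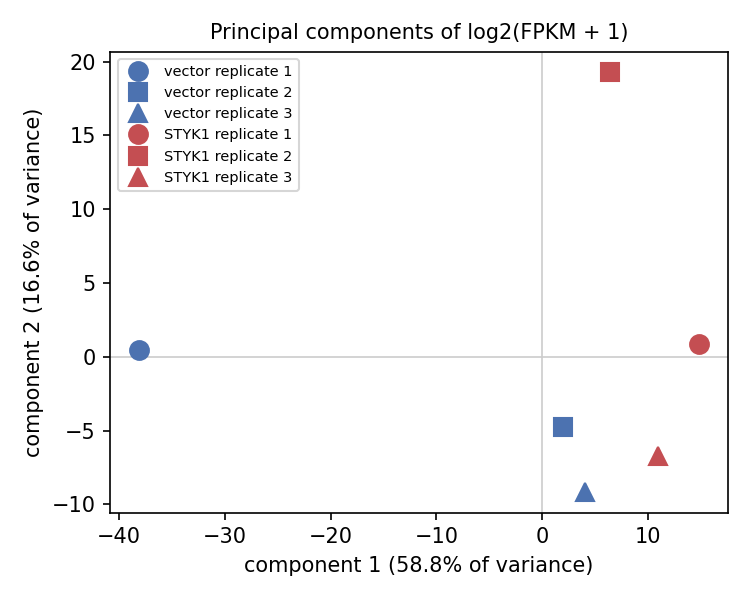
Principal components of log2(FPKM + 1) over 11464 genes, with the component holding 58.8% of the variance on the horizontal axis and the one holding 16.6% on the vertical axis (arbitrary units). Each point is 1 library (blue, vector; red, STYK1; circle, square and triangle for replicates 1, 2 and 3); vector 1 lies at -38.1 and the other 5 libraries lie between 1.98 and 14.8 on the horizontal axis.

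The first measurement was the level of the hamster gene Styk1, which shows endogenous transcripts as well as any counted from the plasmid. Styk1 (NCBI Gene ID 101839917) was listed at 1.5, 1.80 and 1.89 FPKM in vector 1, 2 and 3 and at 2.04, 2.46 and 2.41 FPKM in STYK1 1, 2 and 3. The means were 1.73 ± 0.204 FPKM in vector and 2.30 ± 0.229 FPKM in STYK1 libraries (SD, n = 3 each), a 1.33-fold difference, with all 3 STYK1 libraries above all 3 vector libraries. On the log2(FPKM + 1) scale the difference was 0.28 ± 0.14 (SE), with a 95% interval of -0.05 to 0.60. Styk1 did not pass the test (limma-trend, Benjamini-Hochberg adjusted p = 0.470), and it ranked 2169 of the 11464 tested genes by p. A two-sided exact permutation test gave p = 0.1, the smallest value that 3 libraries against 3 can give. The labels do not name the species of the transfected sequence, so hamster gene models may have counted only part of the reads from the plasmid, and overexpression of STYK1/NOK is not shown by the values of these libraries. Of 1276 genes within 0.5 log2 units of the level of Styk1, 25.5% differed between the groups by at least as much.

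**Figure D2:**
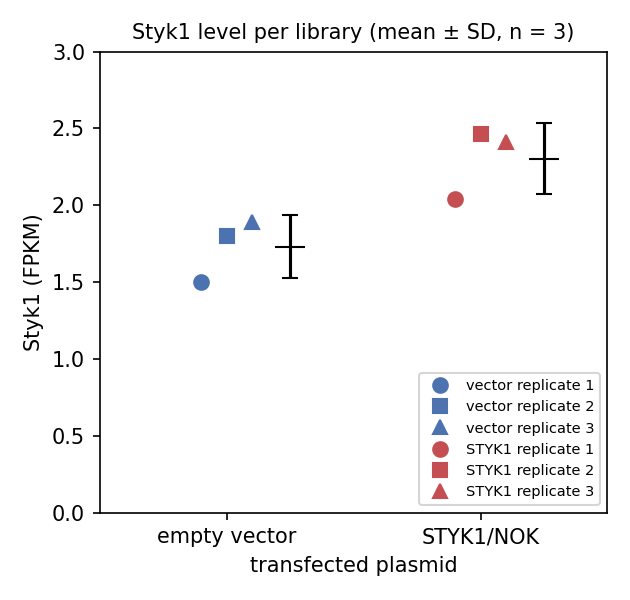
Styk1 in FPKM (vertical axis) in each of the 6 libraries by transfected plasmid (horizontal axis); points are libraries and bars are the mean ± SD of 3 libraries. The 3 STYK1 libraries lie between 2.04 and 2.46 FPKM, above the 3 vector libraries between 1.5 and 1.89 FPKM.

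The comparison the series names is that of STYK1/NOK-transfected with vector-transfected cells across all genes. No gene passed the test (limma-trend, 0 of 11464 genes at an adjusted p under 0.05, smallest adjusted p = 0.469), and the genes named here are given as values. Among the genes with the smallest p, Rab33b, Ccne2 and Pdpk1 had higher means in STYK1 libraries, by 1.65-fold, 1.64-fold and 1.85-fold. Med11, Trappc6a and Endog had lower means, by 1.55-fold, 1.65-fold and 1.74-fold. At an unadjusted p under 0.05 there were 1128 genes (9.84%), 568 higher and 560 lower in STYK1 libraries. That split depended on the scaling: it was 1256 higher and 218 lower when the libraries were scaled to equal FPKM sums, and 402 higher and 762 lower after median centring. The 3 libraries of one group all lay above the 3 of the other for 2646 genes (23.1%), 1564 higher and 1082 lower in STYK1. The average share over all splits of the libraries into 3 and 3 is 10%. Genes are correlated across these libraries, so a single split can lie far from that average. The share in the other splits was not computed, so no excess is shown. The median log2 fold change over all genes was 0.01, and 18 genes were at least 2-fold higher and 16 at least 2-fold lower on the log2(FPKM + 1) scale. Without vector 1 there were again 0 genes at an adjusted p under 0.05 and 1083 at an unadjusted p under 0.05. With libraries weighted by their quality, a choice made after seeing the data that gave vector 1 a weight of 0.129, limma called 24 genes, 6 higher and 18 lower.

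Of the 12 genes with the smallest p among those higher in all 3 STYK1 libraries, 11 are given, as mean ± SD in FPKM, n = 3 in each group. Rab33b, a small GTPase of the Golgi (Gene ID 101827857), measured 11.9 ± 2.16 FPKM in vector and 19.6 ± 2.44 FPKM in STYK1 libraries. Ccne2, which encodes cyclin E2, a partner of CDK2 at the start of DNA replication (Gene ID 101843918), measured 2.71 ± 0.108 against 4.45 ± 0.446 FPKM in the same order. Pdpk1, the kinase that phosphorylates the activation loop of AKT (Gene ID 101835018), measured 3.22 ± 0.988 against 5.96 ± 0.961 FPKM. The log2 differences of these genes were 0.68 ± 0.15 (SE), 0.55 ± 0.13 (SE) and 0.74 ± 0.19 (SE), with unadjusted p-values of 0.00146, 0.00251 and 0.00512. Of genes for chromosome structure and segregation, Smc5 (Gene ID 101839075) measured 16.6 ± 0.289 against 21.1 ± 0.374 FPKM and Ska2, of the spindle and kinetochore associated complex (Gene ID 101843878), measured 11.2 ± 0.965 against 15.1 ± 0.806 FPKM. The centrosomal gene Cep85l (Gene ID 101844917) measured 1.24 ± 0.231 against 2.51 ± 0.439 FPKM. The m6A-binding helicase Ythdc2 (Gene ID 101836015) measured 7.97 ± 0.851 against 10.98 ± 0.505 FPKM. Dcaf17, a factor associated with CUL4 ubiquitin ligases (Gene ID 101841040), measured 2.48 ± 0.370 against 4.57 ± 0.534 FPKM, and Uevld (Gene ID 101839261) measured 5.35 ± 1.13 against 8.99 ± 1.247 FPKM. Chac2, a glutathione-degrading enzyme (Gene ID 101835141), measured 8.30 ± 0.240 against 11.5 ± 0.997 FPKM. Sh3pxd2b, a podosome scaffold (Gene ID 101830664), measured 6.15 ± 0.734 against 8.90 ± 0.606 FPKM.

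The 12 genes with the smallest p among those lower in all 3 STYK1 libraries are given in the same way. Med11, a subunit of the Mediator complex (Gene ID 101844091), had the smallest p of all tested genes, with 23.4 ± 1.70 FPKM in vector and 15.1 ± 0.0608 FPKM in STYK1 libraries. Its log2 difference was -0.60 ± 0.09 (SE), with an unadjusted p of 1.82e-04. Of 5 genes with mitochondrial products, the complex I subunit Ndufb2 (Gene ID 101842033) measured 67.9 ± 6.88 against 47.2 ± 2.35 FPKM and the import subunit Tomm7 (Gene ID 101839709) measured 127 ± 8.80 against 87.3 ± 11.3 FPKM. The mitochondrial ribosomal protein gene Mrpl34 (Gene ID 101836680) measured 104 ± 12.1 against 75.0 ± 4.94 FPKM, and Endog, a mitochondrial nuclease (Gene ID 101827104), measured 15.1 ± 2.69 against 8.67 ± 0.849 FPKM. Ech1, an enzyme of fatty acid oxidation (Gene ID 101830747), measured 68.2 ± 4.62 against 51.3 ± 2.78 FPKM. In the secretory pathway, the vesicle tethering subunit Trappc6a (Gene ID 101836853) measured 29.5 ± 4.06 against 17.9 ± 2.34 FPKM, and Tmem258, of the oligosaccharyltransferase complex (Gene ID 101843805), measured 166 ± 12.1 against 129 ± 2.75 FPKM. Zdhhc12, a palmitoyltransferase (Gene ID 101826318), measured 6.96 ± 0.311 against 4.05 ± 0.836 FPKM. Ten1, of a telomere-binding complex (Gene ID 101824252), measured 10.2 ± 0.637 against 5.53 ± 1.39 FPKM, and the inositol phosphate kinase Ip6k2 (Gene ID 101823291) measured 46.7 ± 1.69 against 36.3 ± 1.01 FPKM. Lime1, an adaptor protein of lymphocyte signalling (Gene ID 101826370), was listed at 1.43, 1.58 and 1.13 FPKM in the vector libraries and at 0.44, 0 and 0 FPKM in STYK1 1, 2 and 3. With quality weights, 8 of the 24 genes chosen by the rule passed the test (adjusted p between 0.0152 and 0.0404, limma-trend): Med11, Trappc6a, Endog, Ten1, Tomm7, Tmem258, Mrpl34 and Ip6k2. The 24 had been chosen by their p in the same libraries, so this is no separate support. Leaving vector 1 out, in place of weighting it, called 0 genes.

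Of 27 gene lists with enough tested members, fixed before the data were examined, 4 were called by camera with its preset correlation at an adjusted p under 0.05. With that preset, ribosomal protein genes and oxidative phosphorylation genes were called lower in STYK1 libraries as sets, and genes of mitosis and of DNA replication higher, but none of the 4 calls held with an estimated correlation (adjusted p = 0.802 for all 4) or with fry (0.448 to 0.701). In every list tested, 0 members passed over all genes and 0 passed when adjusted over the list alone (limma-trend). The calls of both cell-cycle lists also ended without vector 1. Of the 126 genes chosen by the rule, 58 had a log2 fold change smaller by over 1.5 times without vector 1 (21 of these by over 2 times), 2 a larger one by over 1.5 times, 1 the other sign and 65 a value within 1.5 times. The 21 include Myc, Pdgfra, Cd68, Itgav, Bub1, Ccng1, Kif20b and Spred1, at -0.02, 0.03, -0.04, 0.14, 0.15, 0.27, 0.19 and 0.17 without vector 1, against -0.22, 0.26, -0.12, 0.39, 0.38, 0.58, 0.39 and 0.35 with it. Cd14 is 1 of the 2, at -0.18 against -0.08.

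The 67 ribosomal protein genes had a median log2 fold change of -0.30, with 65 of 67 members below 0 (camera adjusted p = 1.73e-20; adjusted p = 0.802 with an estimated correlation). At an unadjusted p under 0.05, 1 member was higher and 35 were lower in STYK1 libraries. Rps18 measured 1958 ± 439 FPKM in vector and 1415 ± 62.9 FPKM in STYK1 libraries, Rpl28 measured 1104 ± 274 against 774 ± 27.1 FPKM and Rps23 measured 705 ± 98.9 against 548 ± 23.8 FPKM. Relative to the vector mean, the list's mean level was 0.25, -0.13 and -0.12 in vector 1, 2 and 3 and -0.32, -0.27 and -0.25 in STYK1 1, 2 and 3, in log2 units. Vector 1, the library that stood apart, was thus the highest of the 6. Without vector 1 the median was -0.16, with 65 of 67 members below 0 (camera adjusted p = 2.78e-29; adjusted p = 0.689 with an estimated correlation), and after quantile normalization it was -0.05. Ribosomal protein genes have many near-identical pseudogene copies, and how reads shared between copies were counted is not given in the sources used here, so the value of any single member is uncertain.

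The 29 oxidative phosphorylation genes had a median log2 fold change of -0.17, with 27 of 29 members below 0 (camera adjusted p = 7.63e-07; adjusted p = 0.802 with an estimated correlation). Of these, 6 were lower and 0 higher at an unadjusted p under 0.05. Ndufb8 and Ndufa4 measured 164 ± 22.4 against 131 ± 3.997 FPKM and 740.3 ± 54.9 against 613 ± 52.9 FPKM, vector against STYK1. Sdhb, of the succinate dehydrogenase complex, measured 149.7 ± 17.3 against 125 ± 3.74 FPKM, and Ndufs8 measured 150.1 ± 13.0 against 123 ± 16.7 FPKM. The list's mean level was 0.16, -0.10 and -0.06 in vector 1, 2 and 3 and -0.21, -0.18 and -0.12 in STYK1 1, 2 and 3. Without vector 1 the median was -0.09 (camera adjusted p = 7.59e-06; adjusted p = 0.689 with an estimated correlation), and it was -0.09 after quantile normalization and -0.06 when the libraries were scaled to equal FPKM sums, a scaling that moved the median of all genes to 0.12.

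The 41 genes of mitosis and G2/M had a median log2 fold change of 0.22, with 39 of 41 members above 0 (camera adjusted p = 8.07e-04; adjusted p = 0.802 with an estimated correlation). At an unadjusted p under 0.05, 2 were higher and 0 lower: the kinetochore motor Cenpe, at 6.41 ± 1.15 against 8.74 ± 0.888 FPKM, and the spindle-associated gene Hmmr, at 13.5 ± 3.99 against 18.9 ± 0.684 FPKM, vector against STYK1. Kif20b and the checkpoint kinase Bub1 measured 8.24 ± 2.04 against 10.9 ± 1.73 FPKM and 10.9 ± 2.96 against 14.2 ± 1.32 FPKM. Relative to the vector mean, the list's level was -0.43 in vector 1, 0.15 in vector 2, 0.27 in vector 3, 0.34 in STYK1 1, -0.02 in STYK1 2 and 0.37 in STYK1 3. Without vector 1 the median was 0.01 (camera adjusted p = 0.981), and the call also ended without STYK1 3 (adjusted p = 0.176).

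The 45 genes of DNA replication and G1/S had a median log2 fold change of 0.14, with 34 of 45 members above 0 (camera adjusted p = 0.0215; adjusted p = 0.802 with an estimated correlation). At an unadjusted p under 0.05, 3 were higher and 0 lower. They were Ccne2, given before, the replication licensing factor Cdc6, at 1.88 ± 0.815 against 3.35 ± 0.600 FPKM, and the DNA polymerase alpha subunit Pola1, at 3.62 ± 1.01 against 5.22 ± 0.0635 FPKM. Cyclin D1 (Ccnd1) measured 19.2 ± 2.81 against 23.3 ± 2.27 FPKM. The list's level was -0.25 in vector 1, 0.10 in vector 2, 0.15 in vector 3, 0.22 in STYK1 1, -0.0036 in STYK1 2 and 0.27 in STYK1 3. The median was 0.03 without vector 1 (camera adjusted p = 0.699). The call also ended without STYK1 1 (adjusted p = 0.106), without STYK1 3 (adjusted p = 0.352) and after quantile normalization (camera adjusted p = 0.0603).

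**Figure D3:**
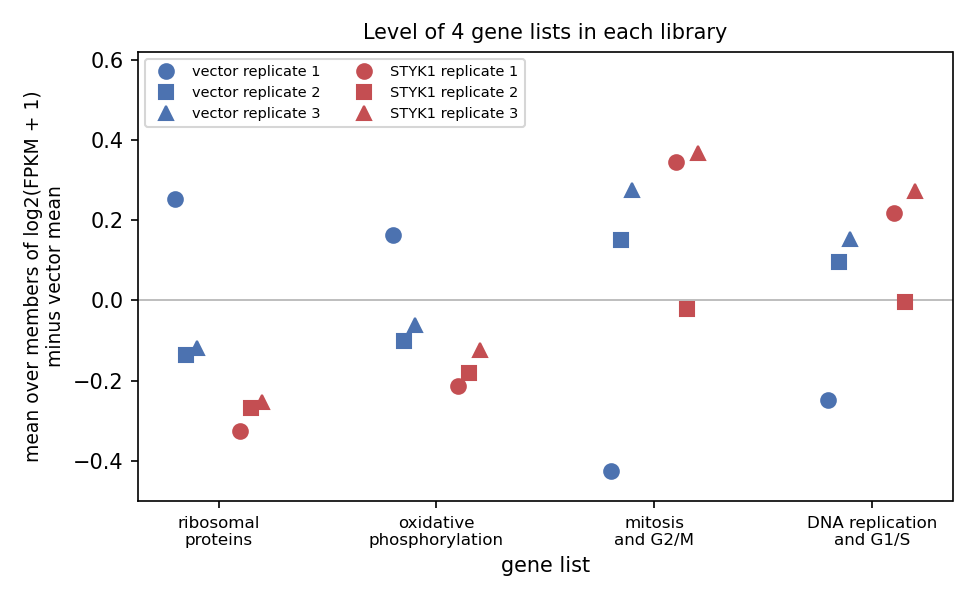
Level of 4 gene lists (horizontal axis) in each of the 6 libraries, as the mean over members of log2(FPKM + 1) minus the vector mean (vertical axis, log2 units; blue, vector; red, STYK1; circle, square and triangle for replicates 1, 2 and 3). Vector 1 is the highest library for ribosomal proteins (0.25) and oxidative phosphorylation (0.16) and the lowest for mitosis (-0.43) and DNA replication (-0.25).

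The other 23 lists did not pass, and their medians are values with no direction called. Of these, 4 were called lower in STYK1 libraries under other settings with the preset correlation: NF-kB and inflammatory genes without vector 1 (adjusted p = 0.0222), without STYK1 2 (0.0416) and with quality weights (0.0394), NRF2 targets without vector 1 (0.0200) and with quality weights (0.0466), autophagy and lysosome genes without STYK1 2 (0.0416), and the integrated stress response without vector 3 (0.0438). None of these calls held under the same settings with an estimated correlation (adjusted p = 0.689 to 0.734) or with fry (0.157 to 0.537). The sign of the median changed for 11 of the 27 lists when the libraries were scaled to equal FPKM sums, for 4 after quantile normalization and for 2 after median centring. Equal sums moved the median of all genes from 0.01 to 0.12, so list medians a little below 0 moved above it. Without vector 1, the medians of 13 of these 23 lists were smaller by over 1.5 times, 3 were larger by over 1.5 times, 3 lay within 1.5 times and 4 had the other sign. The 4 were interferon response (0.05), JAK-STAT3 targets (0.0022), mesenchymal transition (-0.06) and hypoxia and glycolysis (0.02). Of the signalling lists, EGFR, receptor tyrosine kinase and RAS pathway members had a median log2 fold change of 0.15 (25 of 37 members above 0, camera adjusted p = 0.126), and of 0.05 without vector 1, which lay at -0.16 relative to the vector mean. Mapk3, which encodes ERK1, measured 60.0 ± 6.60 FPKM in vector and 49.2 ± 3.32 FPKM in STYK1 libraries, and Map2k2, the kinase above it, measured 90.6 ± 10.7 against 76.1 ± 2.85 FPKM. The PI3-kinase catalytic subunits Pik3cb and Pik3ca measured 6.32 ± 0.976 against 8.50 ± 0.983 FPKM and 34.6 ± 3.95 against 41.3 ± 0.459 FPKM. Immediate-early and ERK pathway genes had a median of -0.02 (23 of 38 members below 0, camera adjusted p = 0.765), with Plaur at 2.31 ± 0.366 against 1.28 ± 0.335 FPKM, Klf6 at 59.3 ± 8.23 against 71.9 ± 4.87 FPKM and the RAS pathway inhibitor Spred1 at 22.7 ± 4.68 against 28.8 ± 1.32 FPKM. FOXO targets had a median of 0.13 (11 of 17 members above 0, camera adjusted p = 0.382), among them the proapoptotic gene Bcl2l11 at 9.19 ± 2.08 against 12.8 ± 1.75 FPKM and the mTOR complex gene Rictor at 8.80 ± 1.94 against 12.01 ± 2.06 FPKM. Targets of JAK-STAT3 had a median of -0.06 (11 of 19 members below 0, camera adjusted p = 0.646), with the kinase gene Pim2 at 16.8 ± 1.07 against 13.9 ± 0.608 FPKM and Cebpd at 177 ± 57.1 against 119 ± 20.9 FPKM. Wnt and beta-catenin targets had a median of 0.09 (5 of 8 members above 0, camera adjusted p = 0.764). Ccnd1, given before, and Ctnnb1, at 123 ± 16.9 against 137 ± 8.15 FPKM, had higher means in STYK1 libraries. Lower means were listed for Bmp4, at 8.34 ± 0.471 against 7.04 ± 0.213 FPKM, and Myc, at 133 ± 33.4 against 113 ± 21.4 FPKM. For Myc, vector 1 was listed at 171 FPKM and vector 2 and 3 at 115 and 112 FPKM. TGF-beta targets had a median of 0.03 (15 of 22 members above 0, camera adjusted p = 0.545), with the SMAD corepressor Skil at 10.4 ± 0.781 against 12.9 ± 1.21 FPKM and Smurf2 at 37.0 ± 3.79 against 43.2 ± 1.73 FPKM.

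NF-kB and inflammatory genes had a median log2 fold change of -0.12 (17 of 23 members below 0, camera adjusted p = 0.0667). The inhibitor of NF-kB Nfkbib measured 86.9 ± 11.5 FPKM in vector and 67.9 ± 1.64 FPKM in STYK1 libraries, and the matrix protease Mmp9 measured 104 ± 2.55 against 87.8 ± 7.15 FPKM. With the preset correlation and without vector 1 this list was called lower in STYK1 libraries (median -0.05, camera adjusted p = 0.0222; adjusted p = 0.689 with an estimated correlation and 0.423 with fry). NRF2 targets had a median of -0.08 (13 of 20 members below 0, camera adjusted p = 0.127), and were also called lower that way without vector 1 (median -0.10, camera adjusted p = 0.0200; adjusted p = 0.689 with an estimated correlation and 0.331 with fry). Ferritin light chain (Ftl) measured 654 ± 124 against 489 ± 37.3 FPKM, and heme oxygenase (Hmox1) measured 60.7 ± 3.80 against 49.9 ± 7.43 FPKM. Interferon response genes had a median of -0.04 and a mean of 0.01 (camera adjusted p = 0.950), so the median differed in sign from the mean and from the test. Ifi35 measured 11.4 ± 1.88 against 7.45 ± 0.680 FPKM and Lgals3bp measured 105 ± 24.6 against 79.0 ± 8.91 FPKM. Genes of the integrated stress response and amino acid synthesis had a median of -0.10 (22 of 30 members below 0, camera adjusted p = 0.126), with the serine synthesis gene Phgdh at 51.4 ± 3.45 against 43.3 ± 1.21 FPKM and Eif4ebp1 at 206 ± 43.0 against 157 ± 7.74 FPKM. Of this list's members, 2 were higher and 2 lower in STYK1 libraries at an unadjusted p under 0.05 (limma-trend). For the unfolded protein response, the median was -0.02, the mean 0.02 and the direction of the test downward (14 members above 0 and 14 below, camera adjusted p = 0.764). Manf, secreted under endoplasmic reticulum stress, measured 162 ± 7.33 against 133 ± 10.1 FPKM. Heat shock and chaperone genes had a median of 0.01 (camera adjusted p = 0.954), with Cryab at 34.7 ± 6.43 against 25.7 ± 2.57 FPKM and Hspa4 at 61.5 ± 0.727 against 71.7 ± 3.64 FPKM. Targets of p53 had a median of 0.09 (16 of 29 members above 0, camera adjusted p = 0.596), with Ccng1 at 38.8 ± 13.0 against 56.0 ± 3.34 FPKM, where vector 1 was listed at 24.1 FPKM, and Apaf1 at 5.93 ± 1.01 against 7.93 ± 1.02 FPKM. Apoptosis regulators had a median of 0.10 (18 of 29 members above 0, camera adjusted p = 0.545; 0.02 without vector 1), with Bcl2 at 3.39 ± 0.745 against 4.59 ± 0.598 FPKM and Bad at 24.7 ± 1.12 against 20.6 ± 2.69 FPKM.

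Of the metabolic lists, cholesterol and fatty acid synthesis had a median log2 fold change of 0.09 (19 of 28 members above 0, camera adjusted p = 0.316). Hmgcs1, which makes HMG-CoA for the mevalonate pathway, measured 10.9 ± 1.19 FPKM in vector and 14.7 ± 0.953 FPKM in STYK1 libraries, and Idi1, Hsd17b7 and Fdps of the same route measured 10.8 ± 1.84 against 15.4 ± 1.33 FPKM, 5.54 ± 0.503 against 7.86 ± 1.28 FPKM and 43.1 ± 5.86 against 35.1 ± 3.54 FPKM. Hypoxia and glycolysis genes had a median of -0.03 and a mean of 0.01, with 13 members above 0, 18 below and the test directed downward (camera adjusted p = 0.596). The glycolytic enzymes Gpi and Aldoa measured 60.0 ± 7.07 against 50.1 ± 3.09 FPKM and 615 ± 62.5 against 533 ± 12.1 FPKM. Autophagy and lysosome genes had a median of -0.06 (26 of 40 members below 0, camera adjusted p = 0.108), with Atg9a at 29.4 ± 4.56 against 21.9 ± 1.30 FPKM and the lysosomal enzyme gene Hexa at 109 ± 3.20 against 96.1 ± 1.81 FPKM. Collagen and matrix genes had a median of 0.09 (14 of 18 members above 0, camera adjusted p = 0.278), with Col5a2 at 30.9 ± 1.38 against 35.2 ± 1.66 FPKM and biglycan (Bgn) at 607 ± 30.6 against 544 ± 17.2 FPKM. Genes of mesenchymal transition and adhesion had a median of 0.01, with the test directed downward (camera adjusted p = 0.927), and the alpha V integrin gene Itgav measured 27.8 ± 7.94 against 35.6 ± 1.34 FPKM, where vector 1 was listed at 18.6 FPKM and vector 2 and 3 at 32.7 and 32.0 FPKM.

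Lists of cell type markers did not pass either. Fibroblast markers had a median log2 fold change of -0.05 over 9 members (camera adjusted p = 0.899), and the growth factor receptor gene Pdgfra measured 263 ± 68.3 FPKM in vector and 309 ± 29.1 FPKM in STYK1 libraries, where vector 1 was listed at 184 FPKM and vector 2 and 3 both at 303 FPKM. Muscle markers had a median of -0.15 (8 of 14 members below 0, camera adjusted p = 0.411; -0.03 without vector 1), with the myosin light chain gene Myl9 at 3.10 ± 0.580 against 2.09 ± 0.263 FPKM. Epithelial markers had 6 tested members and a median of -0.08 (camera adjusted p = 0.509). Among them, the keratin gene Krt7 measured 1.10 ± 0.129 against 0.783 ± 0.186 FPKM. Leukocyte markers also had 6 tested members, with a median of -0.01 (camera adjusted p = 0.827). Cd68 and Cd14 among them measured 315 ± 32.6 against 289 ± 8.65 FPKM and 208 ± 27.2 against 197 ± 24.2 FPKM. Of the endothelial markers 11 were listed and 1 passed the filter on low values, Cdh5, at 6.83 ± 2.07 against 7.56 ± 1.49 FPKM, and that list was not tested. For the lists of mitochondrially encoded genes and histones, 0 symbols were matched among the listed genes, and they were not analysed here.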

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

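Quality weights and scaling to equal FPKM sums were chosen after seeing the data, as was running the lists under the other pseudocounts, scalings and without a filter. The number of genes at an adjusted p under 0.05 was 0 with pseudocounts of 0.1 and 0.01, no filter, quantile normalization, median centring, equal sums, a threshold of 0.01 and a 2-fold minimum, with 1044 to 1474 genes at an unadjusted p under 0.05. It ranged from 0 to 2 over the 6 fits that left out 1 library. It was 2 without vector 3 (Map3k11 and an ID with no name), 2 without STYK1 1 (both with no name) and 2 without STYK1 3 (Dclre1b and an ID with no name), genes chosen after their values were seen. It was 24 with quality weights. The log2 fold change of Styk1 stayed above 0 and did not pass in any of 14 fits with other settings, at 0.18 with quality weights to 0.41 with a pseudocount of 0.01. Residuals of vector and STYK1 libraries with the same number correlated at -0.27, -0.16 and 0.11 across genes, and vector 1 correlated best with STYK1 2 (0.28). Each group was centred on its own mean, which ties these correlations together. They therefore cannot show whether libraries with equal numbers were paired. With the replicate block, 0 genes passed, 831 had an unadjusted p under 0.05 and the same 4 lists were called.

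The number of lists called was 4 in the main result, 0 with an estimated correlation, 0 with fry, 6 with quality weights, 3 after quantile normalization and 2 to 6 with 1 library left out (2 without STYK1 3, 6 without STYK1 2). With an estimated correlation all 4 lists had a camera adjusted p of 0.802, where their members' correlations were 0.79 (ribosomal proteins), 0.50 (oxidative phosphorylation), 0.88 (mitosis) and 0.44 (DNA replication), far above the preset 0.01. With fry the adjusted p was 0.448 for ribosomal proteins and for oxidative phosphorylation, 0.701 for mitosis and 0.630 for DNA replication. After quantile normalization that of DNA replication was 0.0603; the cause was not tested. With 1 library left out, the camera adjusted p ran from 2.78e-29 to 1.55e-16 for ribosomal proteins, from 6.31e-08 to 2.79e-05 for oxidative phosphorylation, from 1.22e-09 to 0.981 for mitosis and from 5.13e-06 to 0.699 for DNA replication. Scaling to equal sums moved the median log2 fold change of all genes to 0.12, against -0.19 for ribosomal proteins, -0.06 for oxidative phosphorylation, 0.33 for mitosis and 0.25 for DNA replication, so none of the 4 changed direction.

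For the 126 genes chosen by the rule under 14 settings, 11 of 1764 log2 fold changes had the opposite sign and 8 passed the test, all 8 with quality weights. The opposite signs were in 5 marker genes: Cd68 (0.00447), Cd14 (0.0162) and Fcer1g (-0.00324) after quantile normalization, Cd14 with equal sums (0.0296) and Cldn3 with quality weights (0.0426). Over the fits with 1 library left out, the value ran from -0.184 to 0.0186 for Cd14, from -0.0714 to 0.229 for Fcer1g, from -0.372 to 0.0220 for Dcn and from -0.234 to 0.0353 for Cldn3. The signs differed without vector 1 or STYK1 3 for Fcer1g, without vector 2 or STYK1 2 for Cd14, without vector 2 for Dcn and without STYK1 3 for Cldn3. The cause was not tested. DESeq2 size factors, total-count scaling, the count filters, the DESeq2 test and limma-voom were planned for counts and not run, because the values are FPKM. Depth is unknown in absolute terms, so how far counting error limits genes of low FPKM, Styk1 among them, is open.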

Other observations

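The calls of gene lists with the preset correlation, with an estimated correlation and with fry in all 6 libraries, and the counts over other splits of the libraries, were planned; the intervals between libraries, the lists by protein size, the tests of vector 1 and of the spread around Styk1, and the choice of genes were made after the results were seen. Among named genes with a mean of at least 20 FPKM, the 12 farthest above vector 2 and vector 3 in vector 1 included Ddit4, Jun, Gadd45b, Nupr1, Bbc3 and Ier2, which were not tested as a group. Relative to the vector mean, the fixed lists for stress and immediate-early genes lay on both sides in vector 1: the integrated stress response at 0.13, p53 targets at 0.06, hypoxia and glycolysis at 0.04, immediate-early and ERK pathway genes at 0.02, apoptosis regulators at 0.02, heat shock genes at 0.0067 and the unfolded protein response at -0.10. Jun measured 79.0 FPKM in vector 1 against 34.3 and 39.0 FPKM in vector 2 and vector 3, and Ddit4, an inhibitor of mTOR complex signalling, measured 92.1 FPKM in vector 1 against 45.9 and 38.7 FPKM in vector 2 and vector 3. In STYK1 2 Jun was also high, at 70.6 FPKM, against 39.9 in STYK1 1 and 36.4 in STYK1 3. Farthest below were Pi15, Nek7 and Ids, with Rrm2, which makes deoxyribonucleotides, and Anln, which acts in cytokinesis, in the same group. Rrm2 measured 12.6 FPKM in vector 1 against 32.4 and 40.7 FPKM in vector 2 and vector 3, and Anln measured 15.7 FPKM in vector 1 against 33.5 and 40.8 FPKM in vector 2 and vector 3. Across the 86 genes of both cell-cycle lists, 79 lay below the mean of vector 2 and vector 3 in vector 1, with a median log2 difference of -0.50.

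Some abundant genes had large differences between the groups without overlap, though none passed the test over all genes. The largest on the log2 scale, among genes with a mean of at least 20 FPKM, was that of LOC101833042, a gene named only by an identifier. It measured 271 ± 101 FPKM in vector and 103 ± 21.8 FPKM in STYK1 libraries, 2.63-fold lower, with a log2 fold change of -1.35, and -1.06 without vector 1. Hp, which encodes the hemoglobin-binding protein haptoglobin, measured 121 ± 44.7 FPKM in vector and 61.4 ± 15.7 FPKM in STYK1 libraries, 1.96-fold lower, and the secreted phospholipase gene Pla2g2a measured 874 ± 229 against 538 ± 40.5 FPKM, 1.62-fold lower. Dpm3, of the dolichol phosphate mannose synthase, measured 41.4 ± 17.0 against 21.6 ± 3.29 FPKM. Actr2, of the actin-nucleating ARP2/3 complex, measured 52.0 ± 17.6 against 83.7 ± 6.29 FPKM, 1.61-fold higher in STYK1 libraries. In Hp, Pla2g2a and Dpm3 vector 1 was the highest of the 6 libraries and in Actr2 the lowest, at 172, 1139, 61.0 and 32.2 FPKM. Without vector 1 the log2 fold changes of Hp, Pla2g2a, Dpm3 and Actr2 were -0.65, -0.46, -0.54 and 0.43, against -0.93, -0.67, -0.85 and 0.74 with it. Pla2g2a was among the 24 genes called with quality weights.

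Ribosomal protein and oxidative phosphorylation genes were called lower in STYK1 libraries by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.802 for both lists) or with fry (adjusted p = 0.448 for both). Between libraries, the mean level differed by -0.28 (95% interval -0.64 to 0.07) for ribosomal proteins and by -0.17 (-0.41 to 0.07) for oxidative phosphorylation. Without vector 1 it differed by -0.16 (-0.25 to -0.06, median log2 fold change -0.16, adjusted p = 0.246 with fry) and by -0.09 (-0.21 to 0.025) in the same order. Of these 4 intervals 1 leaves out 0, and none lies wholly under the bound of -0.1 set for excluding vector 1 as the only source. For ribosomal proteins, the levels of STYK1 1 to 3 (-0.32, -0.27 and -0.25) all lay below those of vector 2 and 3 (-0.13 and -0.12). With the interval that leaves out 0, these values lean against vector 1 as the only source of the ribosomal difference, but do not settle it. That interval was chosen after the results were seen and is not adjusted for the number of lists, and the bound is not met. Without vector 1 the list was also not called by fry or by camera with an estimated correlation (adjusted p = 0.689). For oxidative phosphorylation, whether vector 1 alone accounts for the difference cannot be told. A median of -0.18 was found for 81 genes for short proteins outside the ribosome and the respiratory chain, such as Mif and Polr2i (67 below 0; interval of the mean level -0.39 to 0.05, and -0.29 to 0.09 without vector 1), and one of 0.22 for 64 genes for very large proteins, such as Golgb1 and Ranbp2 (62 above 0; 0.01 to 0.44, and -0.04 to 0.38 without vector 1). The short-protein median was -0.11 without vector 1, -0.09 after quantile normalization, where that of ribosomal proteins was -0.05, and -0.07 with equal FPKM sums, where that of all genes was 0.12; the large-protein median was 0.16, 0.18 and 0.34 in the same order, and vector 1 minus the mean of vector 2 and vector 3 was 0.26 for short and -0.18 for large proteins, while vector 3 minus vector 2 was 0.03 and -0.03. Because these lists were written after fold changes in the same libraries had been compared with gene spans, they do not test a size-linked difference, which stays open, as does an untested effect of STYK1 on these genes.

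The cell-cycle lists were called higher in STYK1 libraries by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.802 for both lists) or with fry (adjusted p = 0.701 for mitosis and 0.630 for DNA replication). Whether vector 1 alone accounts for this cannot be told: without it, the median log2 fold change over the 86 genes of both lists was 0.0168, with 49 above 0 and 37 below, and the mean level differed by 0.03 (95% interval -0.41 to 0.47 between libraries), against 0.19 (-0.35 to 0.74) with it, so both intervals include 0 and neither decides. Whether vector 1 differed through its culture, its RNA or its library cannot be read from the labels, and an effect of STYK1 inside that interval is not excluded.

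Styk1 itself was 1.33-fold higher in STYK1 libraries, which does not show overexpression from the plasmid. Of 1276 genes within 0.5 log2 units of it, 25.5% differed by as much, so Styk1 did not stand out from genes at that level. Those differences come from the same comparison and would hold any effect of STYK1/NOK and of vector 1. They therefore cannot tell whether the rise is only spread between libraries, which stays open. A transfected sequence that hamster gene models count only in part stays open as well, since the plasmid's sequence was not used here.

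There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 1128 genes at an unadjusted p under 0.05, and the highest of the others gave 918, so 1 split of 10 gave a count as large. The real split gave 0 genes at an adjusted p under 0.05, and the highest of the others gave 1; since any count reaches 0, the 10 of 10 splits with a count as large test nothing. For the lists the real split gave 4 calls and the highest of the others 6, and 5 of the 10 gave as many.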
